A study of Homo sapiens with 11 samples.

How the data were processed

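Total RNA of T-47D cells, an established human breast cancer cell line, was measured on 11 Agilent 2-colour whole human genome oligonucleotide arrays. Per the labels' protocols, cells were given 0.3 Gy at a low dose rate of 0.3 Gy/h for 1 h and cultured for 2 months (called LDR here), or given 0.3 Gy at a high dose rate of 35 Gy/h and harvested 24 h later (HDR). Control cells were untreated and harvested after several passages. The cells were scraped into RNAlater, and RNA was purified with the Qiagen RNeasy kit and labelled by the Agilent Quick Amp protocol, per the labels. The first set of 4 arrays set LDR (Cy5) against the control (Cy3), another 4 set HDR (Cy5) against the control (Cy3), and the last 3 set HDR (Cy5) against LDR (Cy3). No array had its dyes swapped. The labels call the arrays of each set biological replicates.

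The deposited intensity values, mean pixel signals of each spot and median pixel signals of its local background, came from Agilent Feature Extraction 9.1.3.1 without background subtraction, per the file headers. The same files held processed intensity values that the scanner software had background-subtracted, detrended and dye-normalized by lowess, and their log10 ratio of Cy5 over Cy3, per the file headers. A table of log2 ratios had been deposited by the authors; its scale, centring and direction were not stated and were found from the values. Each of its columns had a median near 0 and lay within 0.003 log2 units of the loess-normalized ratio of the mean signals without background correction, with the sign of Cy5 over Cy3. The submitters' processing notes name limma, with no version or settings. Spot flags for signal well above background, saturation and non-uniformity were deposited with the intensity values, per the file headers.

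Mean signals were corrected with the normexp method of limma 3.58.1 in R 4.3.3 (offset 50, local background medians) and normalized within each array by loess, with the 1639 control spots at weight 0. Text files were read with the R package data.table, version 1.17.8. Spots with a non-uniformity flag were set to missing (6 to 70 per array); saturated spots were kept. The 43376 remaining spots held 41000 distinct probes, and spots of one probe were averaged. A probe was kept if it was well above background in at least 1 channel on at least 3 arrays of at least 1 comparison, which left 28456 probes. The gene table used for names matched 23958 probes by accession, 2755 by symbol and 1032 by an older symbol; 13255 probes kept the name in the file. Where a gene had more than 1 probe kept (5580 genes), the probe with the highest average intensity stood for it. In this way 20991 genes were tested, 13952 of them with a current symbol. Genes with both channels not well above background, or both saturated, on every array of a comparison stayed in its tests and counts, and no fold is given for them in that comparison. They were 220, 0 and 0 not well above background and 0, 123 and 44 saturated among the genes called in LDR against control, HDR against control and HDR against LDR.

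A linear model in limma with 1 mean for each of the 3 sets of arrays was fitted over all 11 arrays, followed by empirical Bayes moderation (prior SD 0.132 log2 units, 3.88 prior and 8 residual degrees of freedom) and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05, and adjusted p-values of genes in the text are those of limma. Since every comparison had the same dye layout, the sets were also combined into estimates in which a dye effect common to all arrays cancels. HDR against LDR through the control was the HDR against control ratio minus the LDR against control ratio. LDR against control was estimated as the HDR against control ratio minus the HDR against LDR ratio. HDR against control was estimated as 2 times its own ratio minus both other ratios. Each of these estimates adds up the errors of several ratios and is less precise than the direct ratio. A call lost in such an estimate therefore does not by itself point to a dye effect. The closure residual was the LDR against control ratio plus the HDR against LDR ratio minus the HDR against control ratio. It would be 0 without effects of dye, slide, RNA extract or saturated spots.

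Choices made before the data were examined were the model, the filter, the rule for named genes, 22 gene lists and all alternatives but 4. Genes named for a comparison were the 12 with the largest rise and the 12 with the largest fall among called genes with a symbol that had one sign on every array of the comparison and the same sign at an unadjusted p under 0.05 in the dye-free estimate. Up to 4 called members of each list with the smallest p, and the nitric oxide synthase genes whatever their values, were added. Lists were tested with camera in limma at a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. The lists covered the unfolded protein and amino acid stress response, hypoxia and glycolysis, DNA replication and G1/S, G2/M and mitosis, DNA double-strand break signalling and repair, replication-dependent histones, p53 target genes, the BCL2 family and caspases, antioxidant and NRF2 target genes, nitric oxide synthases and their partners, the type I interferon response, NF-kappaB and inflammatory secreted factors, immediate early genes, TGF-beta signalling, oestrogen and progesterone receptor signalling, cholesterol synthesis, heat shock chaperones, metallothioneins, cytoplasmic ribosomal proteins, luminal breast epithelium markers, basal and mesenchymal markers, and blood and endothelial cell markers.

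Each slide held arrays of 1 comparison, and the arrays of HDR against LDR were scanned on another day than the rest, per the file headers, so slide and comparison cannot be told apart. Replicate numbers were checked for pairing through the deviations of arrays from their set's mean. Arrays of LDR and of HDR against the control with the same number deviated together (correlations 0.4, 0.33, 0.62 and 0.4 across genes for numbers 1 to 4), so the numbers were taken to pair these 8 arrays; the labels do not state a pairing. The numbers of the HDR against LDR arrays were not taken to pair with either set (correlations -0.06 to 0.15). Numbers 1 and 2 correlated with HDR against control at 0.15 and 0.12, above arrays of other numbers (-0.1 to -0.05 and -0.1 to -0.06). Number 3 did not (-0.02, other numbers -0.11 to 0.11), so a weak pairing is not excluded. The share of probes well above background was 61.3% to 69% per array in Cy5 and 54.8% to 71.6% in Cy3, and the number of arrays limits the precision.

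The fit was tested on simulated data made from the real spreads of the 20991 genes, around no difference, with 200 genes changed by a known fold. In LDR against control it called 5.5%, 95.5% and 100% of genes changed 1.2-fold, 1.5-fold and 2-fold. In HDR against control it called 0%, 95.5% and 99%, in HDR against LDR 0%, 91.5% and 97.5%, and in HDR against LDR through the control 0%, 83% and 98.5%. At 1.5-fold and 2-fold, 8 to 15 unchanged genes were also called. Far more genes were called in the data (12850 in LDR against control), which makes the adjusted threshold less strict. These shares therefore do not tell how small a difference could be called there.

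Alternatives were no background correction, normexp with offset 10, the scanner software's log ratio, the authors' values, median centring instead of loess, Aquantile normalization between arrays, other filters on dim probes, outlier spots kept, every probe on its own, the mean of a gene's probes, another empirical Bayes setting, separate fits, array weights, the replicate number as a block, a joint fit of direct and indirect evidence, a 1.5-fold minimum and leaving out each array. A block over the 8 control arrays only, a 2-fold minimum, and counts and lists without saturated probes were added after seeing the data. Gene families named by a shared symbol were also chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15. NOS2 was left out of the tests because its probe was not well above background in any of the 22 channels.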

Results

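RNA levels were compared between T-47D breast cancer cells of 3 kinds: untreated control cells, cells given 0.3 Gy at a low dose rate and cultured for 2 months (LDR), and cells given 0.3 Gy at a high dose rate and harvested 24 h later (HDR). Each of 11 arrays carried RNA of 2 kinds, with 4 arrays of LDR against control, 4 of HDR against control and 3 of HDR against LDR. Between 54.8% and 71.6% of probes were well above background in a channel. Log2 ratios of the tested genes had an SD of 0.479 to 0.538 per array in LDR against control, 0.444 to 0.527 in HDR against control and 0.172 to 0.265 in HDR against LDR. Across genes, arrays of 1 comparison correlated at 0.8 to 0.95, 0.76 to 0.88 and 0.57 to 0.73, in the same order. Values are mean log2 ratios with the SD over arrays, n = 4 for either comparison with the control and n = 3 for HDR against LDR.

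The study's title asks about nitric oxide synthase activity, so the genes of these enzymes come first. NOS3, the endothelial nitric oxide synthase, was well above background in all 22 channels and was called in none of the comparisons. Its log2 ratio was 0.11 ± 0.08 in LDR against control (95% interval 0.01 to 0.21, limma adjusted p = 0.0585), 0.04 ± 0.03 in HDR against control (-0.06 to 0.14, adjusted p = 0.47) and 0.01 ± 0.06 in HDR against LDR (-0.1 to 0.13, adjusted p = 0.927). The first of these passed the threshold in several alternatives, among them when array weights were used (adjusted p = 0.0127) and when replicate 2 of LDR against control was left out (adjusted p = 0.0181). NOS1, the neuronal enzyme, was not well above background in either channel on any array of LDR against control or of HDR against LDR. It passed the threshold in LDR against control (adjusted p = 0.0361) and stays in that count, but no fold is given for it. In HDR against control its log2 ratio was -0.01 ± 0.06 (95% interval -0.12 to 0.09, adjusted p = 0.83). NOS2, the inducible enzyme, was not well above background in any channel. Among 23 measured synthases and partners, 3 were higher and 12 lower in LDR than in the control, and 3 were higher and 15 lower in HDR. CALM2, whose calmodulin protein activates the synthases, fell in LDR (-0.7 ± 0.17) and in HDR (-0.89 ± 0.24). DDAH2, which breaks down endogenous inhibitors of the synthases, fell in LDR (-0.84 ± 0.06), and DYNLL1, a binding partner of NOS1, fell in HDR (-0.52 ± 0.13). ASS1, which recycles citrulline to the substrate arginine, rose in both (1.13 ± 0.26 in LDR and 1.09 ± 0.16 in HDR). The list as a set did not pass camera in LDR (adjusted p = 0.109), but did in the dye-free estimate, where it was lower (adjusted p = 0.035; adjusted p = 0.3 with an estimated correlation). In HDR it was lower (adjusted p = 0.0359; adjusted p = 0.322 with an estimated correlation), a call also lost in the dye-free estimate (adjusted p = 0.0588) and without saturated probes (adjusted p = 0.153). Between HDR and LDR, GCHFR, a regulator of the synthesis of the cofactor tetrahydrobiopterin, was higher in HDR (0.37 ± 0.04). In all, 1 member was higher and 1 lower there, and the list did not pass camera (adjusted p = 0.6).

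LDR against control asks which transcripts differed from unirradiated cells 2 months after a low-dose-rate exposure. DDIT3, the stress transcription factor CHOP, had the largest rise among named genes (3.41 ± 0.24, a 10.6-fold increase, adjusted p = 2.36e-09). LAMP3, a lysosomal membrane protein, rose by 3.18 ± 0.1, and GDF15, a stress-induced secreted factor, by 2.96 ± 0.1. CDC25A, the phosphatase that drives entry into S phase, fell by 2.04 ± 0.14 (adjusted p = 2.18e-07), and UHRF1, which keeps DNA methylation through replication, by 2.01 ± 0.13. In all, 12850 of 20991 genes were called, 6009 higher and 6841 lower in LDR. Of these, 1059 had at least a 2-fold difference (535 higher, 524 lower).

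Other large rises in LDR were those of the vasodilator peptide gene ADM (2.65 ± 0.42), the chaperone CLGN (2.64 ± 0.09), the chemokine receptor CXCR4 (2.63 ± 0.32), NEUROG3 (2.61 ± 0.89), and KLHDC7B (2.58 ± 0.13). They were followed by the hypoxia-responsive NDRG1 (2.51 ± 0.13), HERPUD1 of endoplasmic reticulum degradation (2.51 ± 0.05), DDIT4, an inhibitor of mTORC1 (2.5 ± 0.24), and the HIF regulator CITED2 (2.39 ± 0.2). Other large falls were those of SAPCD1 (-2.02 ± 0.74), the S-phase transcription factor E2F2 (-1.96 ± 0.14), TYMSOS (-1.83 ± 0.23), mitochondrial ND6 (-1.82 ± 0.54), and LMBRD2 (-1.76 ± 0.33). Close to these lay the mitotic survivin gene BIRC5 (-1.76 ± 0.06), MAP6D1 (-1.73 ± 0.12), the helicases RECQL4 (-1.72 ± 0.2) and PIF1 (-1.71 ± 0.49), and RASL10A (-1.69 ± 0.79). The other 3 probes of LMBRD2 gave 0.41, 0.42 and 0.16. In the dye-free estimate NEUROG3 (1.12, adjusted p = 0.0852) and ND6 (-0.78, adjusted p = 0.0624) were no longer called.

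Of 30 measured genes of the unfolded protein and amino acid stress response, 27 rose in LDR and none fell (camera adjusted p = 5.41e-14, and adjusted p = 0.00288 with an estimated correlation). The protein disulfide isomerase PDIA4 rose by 2.24 ± 0.12 and the chaperone DNAJB9 by 1.96 ± 0.13. Of 30 hypoxia and glycolysis genes, 26 rose and 1 fell (adjusted p = 3.15e-12; adjusted p = 0.0524 with an estimated correlation). Among them were hexokinase HK2 (1.76 ± 0.1), the pyruvate dehydrogenase kinase PDK1 (1.7 ± 0.15) and the histone demethylase KDM3A (1.53 ± 0.12). Of 28 immediate early genes, 20 rose and 5 fell (21 and 5 adjusted over the list alone; adjusted p = 0.000161, and adjusted p = 0.225 with an estimated correlation). JUN rose by 1.85 ± 0.38 and ATF3 by 1.6 ± 0.24. Luminal breast epithelium markers rose for 15 of 23 genes and fell for none (adjusted p = 0.000143; adjusted p = 0.122 with an estimated correlation). The epithelial transcription factor ELF3 rose by 2.2 ± 0.16 and the splicing factor ESRP1 by 0.99 ± 0.08. TGF-beta signalling genes rose for 14 of 24 and fell for 1 (adjusted p = 0.00168; adjusted p = 0.0626 with an estimated correlation), among them ID2 (1.29 ± 0.29) and the receptor gene ACVR1 (0.45 ± 0.05).

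DNA replication and G1/S genes fell for 29 of 30 measured in LDR (adjusted p = 1.1e-13; adjusted p = 0.0717 with an estimated correlation). The replicative helicase genes GINS2 and MCM3 fell by 1.49 ± 0.14 and 1.43 ± 0.16, and cyclin CCNE1 by 1.19 ± 0.1. Of 31 G2/M and mitosis genes 29 fell, 30 adjusted over the list alone (adjusted p = 6.66e-12; adjusted p = 0.0717 with an estimated correlation), among them the mitotic kinase PLK1 (-1.19 ± 0.07). DNA double-strand break signalling and repair genes fell for 20 of 30 and rose for 3 (adjusted p = 0.00103; adjusted p = 0.0752 with an estimated correlation). The checkpoint mediator MDC1 fell by 1.26 ± 0.17 and RAD54L, a motor protein of homologous recombination, by 1.02 ± 0.11. The 8 lists given so far kept the sign of their median under each of the other 4 scalings. These were no background correction, the scanner software's log ratio, the authors' values and median centring alone. No background correction and the authors' values gave nearly the same ratios, so they are not separate checks. The remaining lists did not pass camera. Replication-dependent histones were higher for 12 and lower for 6 of 20 (adjusted p = 0.0656, and 0.0415 without saturated probes, or adjusted p = 0.556 with an estimated correlation), with H4C14 at 1.31 ± 0.06. In the dye-free estimate 3 were higher and 6 lower, and the median turned from 0.27 to -0.173 (adjusted p = 0.883). The histone list also passed camera in the closure (adjusted p = 0.000226; adjusted p = 0.858 with an estimated correlation). Of 30 type I interferon response genes 6 rose and 17 fell (adjusted p = 0.0539, and 0.0422 in the dye-free estimate, or adjusted p = 0.526 with an estimated correlation): IRF1 rose (1.16 ± 0.09), and the antiviral genes OAS3 (-1.14 ± 0.07) and MX1 (-1.11 ± 0.22) fell. Of 30 p53 target genes 15 rose and 10 fell (adjusted p = 0.283), with GADD45A at 1.4 ± 0.15 and TIGAR, a regulator of glycolysis, at -0.84 ± 0.06.

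Antioxidant and NRF2 target genes rose for 15 and fell for 5 of 35 in LDR (adjusted p = 0.0523, and 0.0455 without saturated probes, or adjusted p = 0.281 with an estimated correlation), cholesterol synthesis genes for 7 and 11 of 29 (adjusted p = 0.684), and BCL2 family and caspase genes for 12 and 10 of 28 (adjusted p = 0.822). NF-kappaB and inflammatory secreted factors had 10 higher and 7 lower of 21 (adjusted p = 0.684), oestrogen and progesterone receptor signalling 10 and 9 of 28 (adjusted p = 0.779), heat shock chaperones 5 and 7 of 19 (adjusted p = 0.873), and metallothioneins 2 and 7 of 12 (adjusted p = 0.429). Cytoplasmic ribosomal protein genes had 1 higher and none lower of 35 (adjusted p = 0.671, and 4.22e-11 in the dye-free estimate, or adjusted p = 0.266 with an estimated correlation, with most probes saturated), basal and mesenchymal markers 3 and 7 of 17 (adjusted p = 0.684), and blood and endothelial cell markers 4 and 2 of 12 (adjusted p = 0.566). In the dye-free estimate 91.9% of the 12850 called genes had the same direction and 7257 were also called, while 111 were called in the opposite direction. Of the 1059 genes with at least a 2-fold difference, 1055 kept their direction in it. That estimate is less precise than the direct ratio, so calls can be lost in it without a dye effect.

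**Figure D1:**
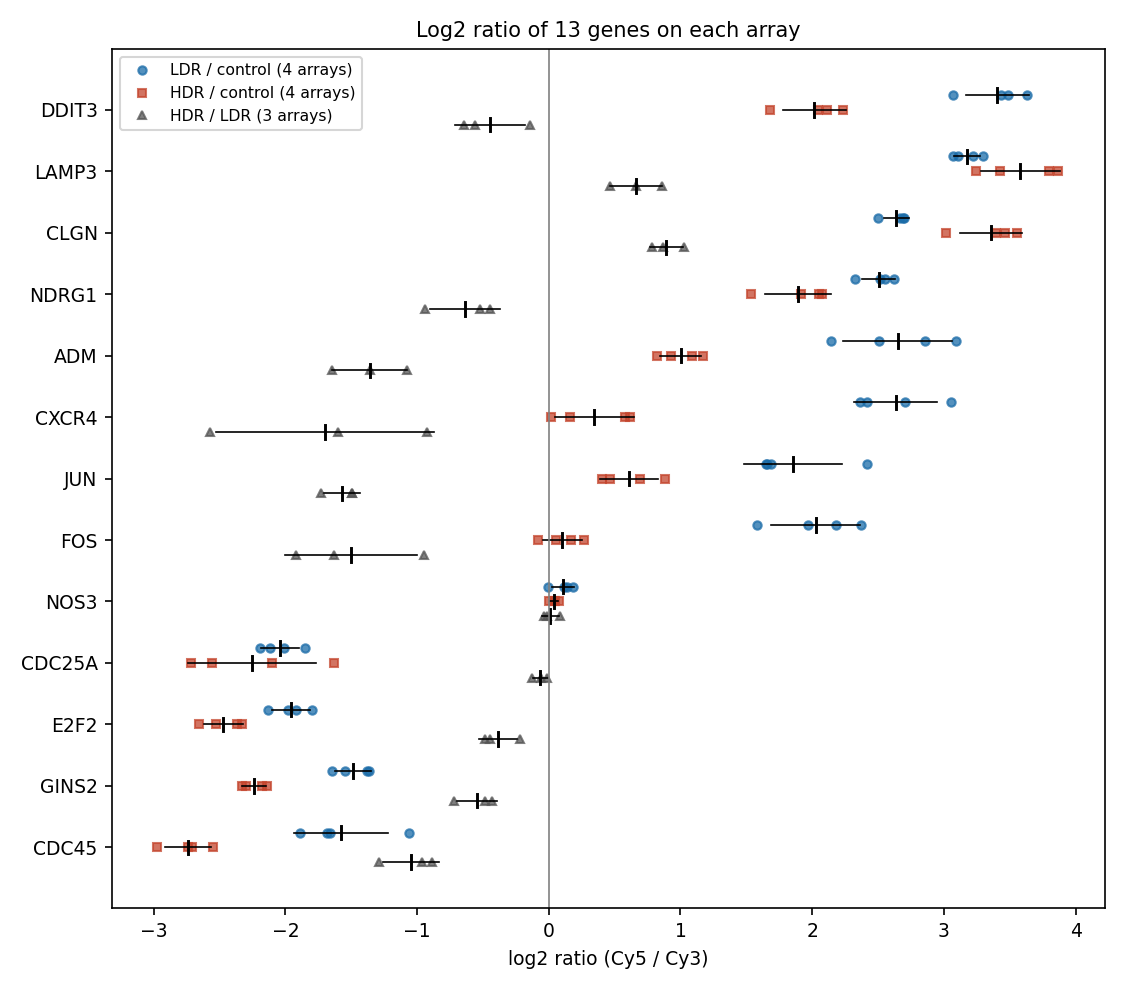
Log2 ratios of 13 genes on each array (x axis, Cy5 over Cy3), with circles for LDR over control, squares for HDR over control and triangles for HDR over LDR; ticks mark means and lines the SD. DDIT3 averaged 3.41 in LDR over control, and the 3 NOS3 means lay between 0.01 and 0.11.

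HDR against control asks which transcripts differed from unirradiated cells 24 h after a high-dose-rate exposure. CDC45, a part of the replicative helicase, fell by 2.74 ± 0.17 (adjusted p = 8.91e-09), the calcium-binding S100A8 by 2.57 ± 0.34 and E2F2 by 2.47 ± 0.15. LAMP3 rose by 3.58 ± 0.3 (adjusted p = 8.3e-10), CLGN by 3.36 ± 0.24, and HSPA5, the main endoplasmic reticulum chaperone BiP, by 2.64 ± 0.24. In all, 12284 of 20987 genes were called, 5642 higher (45.9%) and 6642 lower. With median centring in place of loess, 25.5% of the called genes were higher and the median of all genes lay at -0.13. The scanner software's log ratio put 51.6% of the called genes higher. At least a 2-fold difference was found for 909 genes (319 higher, 590 lower).

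Further rises in HDR were those of the stem cell receptor LGR4 (2.59 ± 0.35), the iron-binding LCN2 (2.43 ± 0.2), the cadherin CDH15 (2.38 ± 0.3), and TEX19 (2.35 ± 0.13). They were followed by CITED2 (2.32 ± 0.13), CYP2B6 (2.23 ± 0.38), the apoptosis effector BAX (2.22 ± 0.53), the peroxisomal PEX10 (2.18 ± 0.24) and NIBAN1 (2.12 ± 0.25). Probes disagreed for BAX, whose other 2 probes gave -0.42 and -0.41, and for PEX10, whose other probe gave -0.13. The dye-free estimates of LGR4 and PEX10 were 4.74 and 3.82. Values above the direct ratio arise where the other 2 comparisons add up to less than it, so they do not strengthen these rises. For both genes the other 2 comparisons thus added up to a smaller rise, which leaves the size of the direct ratio in doubt. For PEX10, LDR against control gave 0.92 and HDR against LDR gave -0.37. Further falls were those of CDC25A (-2.25 ± 0.49), the kinetochore genes SPC25 (-2.25 ± 0.17) and ZWINT (-2.09 ± 0.19), MCM3 (-2.24 ± 0.12) and GINS2 (-2.24 ± 0.09). Close to these lay TEDC2 (-2.18 ± 0.32), SAPCD1 (-2.08 ± 0.66), UHRF1 (-2.06 ± 0.25) and the ubiquitin ligase adaptor DTL (-2.05 ± 0.28).

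All 30 DNA replication and G1/S genes measured fell in HDR (adjusted p = 5.46e-18; adjusted p = 0.0582 with an estimated correlation), with MCM6 at -2.04 ± 0.13. Of 31 G2/M and mitosis genes 30 fell (adjusted p = 2.04e-15; adjusted p = 0.0582 with an estimated correlation), among them the spindle checkpoint gene MAD2L1 (-2.04 ± 0.08) and BIRC5 (-1.71 ± 0.21). Double-strand break signalling and repair genes fell for 21 and rose for 4 of 30 (adjusted p = 0.000207; adjusted p = 0.066 with an estimated correlation). The helicase BLM fell by 1.21 ± 0.09 and the checkpoint kinase CHEK1 by 1.45 ± 0.08. Replication-dependent histones fell for 12 of 20 and rose for none (adjusted p = 0.0193; adjusted p = 0.41 with an estimated correlation), with the linker histone H1-3 at -1.69 ± 0.43 and H4C2 at -1.41 ± 0.56. Unfolded protein and amino acid stress response genes rose for 28 of 30 and fell for none (adjusted p = 2.65e-15, and adjusted p = 0.00235 with an estimated correlation), with PDIA4 at 2.03 ± 0.13 and HYOU1 at 1.93 ± 0.23. Hypoxia and glycolysis genes rose for 22 and fell for 2 of 30 (23 and 3 adjusted over the list alone; adjusted p = 6.93e-07, and adjusted p = 0.099 with an estimated correlation). NDRG1 rose by 1.89 ± 0.25, ANGPTL4 by 1.76 ± 0.27 and HK2 by 1.64 ± 0.19. Luminal markers rose for 14 and fell for 2 of 23 (adjusted p = 0.000387; adjusted p = 0.191 with an estimated correlation), with ELF3 at 1.25 ± 0.16 and ESRP1 at 0.89 ± 0.12.

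Oestrogen and progesterone receptor signalling genes rose for 15 and fell for 3 of 28 in HDR (adjusted p = 0.0193; adjusted p = 0.219 with an estimated correlation), and the list's median of 0.2 was 0.08 relative to all genes with median centring alone (raw -0.05). RARA rose by 1.22 ± 0.27, and the glucocorticoid and progesterone target FKBP5 fell by 1.12 ± 0.15. Cholesterol synthesis genes rose for 5 and fell for 13 of 29 (adjusted p = 0.0359; adjusted p = 0.41 with an estimated correlation; adjusted p = 0.0551 without saturated probes), with mevalonate kinase MVK at -1.47 ± 0.25 and EBP at -1.36 ± 0.19. NF-kappaB and inflammatory secreted factors rose for 3 and fell for 12 of 21 (adjusted p = 0.0359; adjusted p = 0.436 with an estimated correlation), with the same loss without saturated probes (adjusted p = 0.0551). The values included the lymphotoxin gene LTB at -1.31 ± 0.26 and the chemokine CCL2 at -1.03 ± 0.4. Cytoplasmic ribosomal protein genes were higher for 28 and lower for 3 of 35 (adjusted p = 8.36e-06; adjusted p = 0.41 with an estimated correlation), but 30 of the 35 probes were saturated on at least 1 array, and the median of the rest was -0.331. The remaining lists did not pass camera: p53 target genes had 13 higher and 8 lower of 30 (adjusted p = 0.0649, and 0.0326 in the dye-free estimate, or adjusted p = 0.157 with an estimated correlation), with TP53INP1 at 1.19 ± 0.13 and GADD45A at 1.28 ± 0.25. GDF15 was measured on 1 of the 4 arrays (3.13). Type I interferon response genes had 9 higher and 13 lower of 30 (adjusted p = 0.485), with OAS3 at -1.49 ± 0.26 and ISG15 at -0.99 ± 0.11. Immediate early genes had 13 and 6 of 28 (adjusted p = 0.0649), with MYC at 1.01 ± 0.16, and antioxidant and NRF2 target genes 14 and 5 of 35 (adjusted p = 0.0649). AKR1C3 rose by 0.72 ± 0.08, and the antioxidant list's median of 0.08 was 0.05 relative to all genes with median centring alone (raw -0.08). That median turned negative in the dye-free estimate.

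TGF-beta signalling genes had 12 higher and 3 lower of 24 in HDR (adjusted p = 0.0649), metallothioneins 2 and 7 of 12 (adjusted p = 0.102, and 0.0381 in the dye-free estimate, or adjusted p = 0.444 with an estimated correlation), and BCL2 family and caspase genes 8 and 10 of 28 (adjusted p = 0.891). Heat shock chaperones had 3 and 7 of 19 (adjusted p = 0.891), basal and mesenchymal markers 5 and 6 of 17 (adjusted p = 0.902), and blood and endothelial cell markers 2 and 2 of 12 (adjusted p = 0.92). In the dye-free estimate 94.8% of the 12284 called genes kept their direction, 4732 were also called and 6 were called in the opposite direction. That estimate holds 2 times the same HDR against control ratio, so a kept direction is largely built in and is not independent agreement. The estimate is also less precise than the direct ratio, so the lost calls need not reflect a dye effect.

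**Figure D2:**
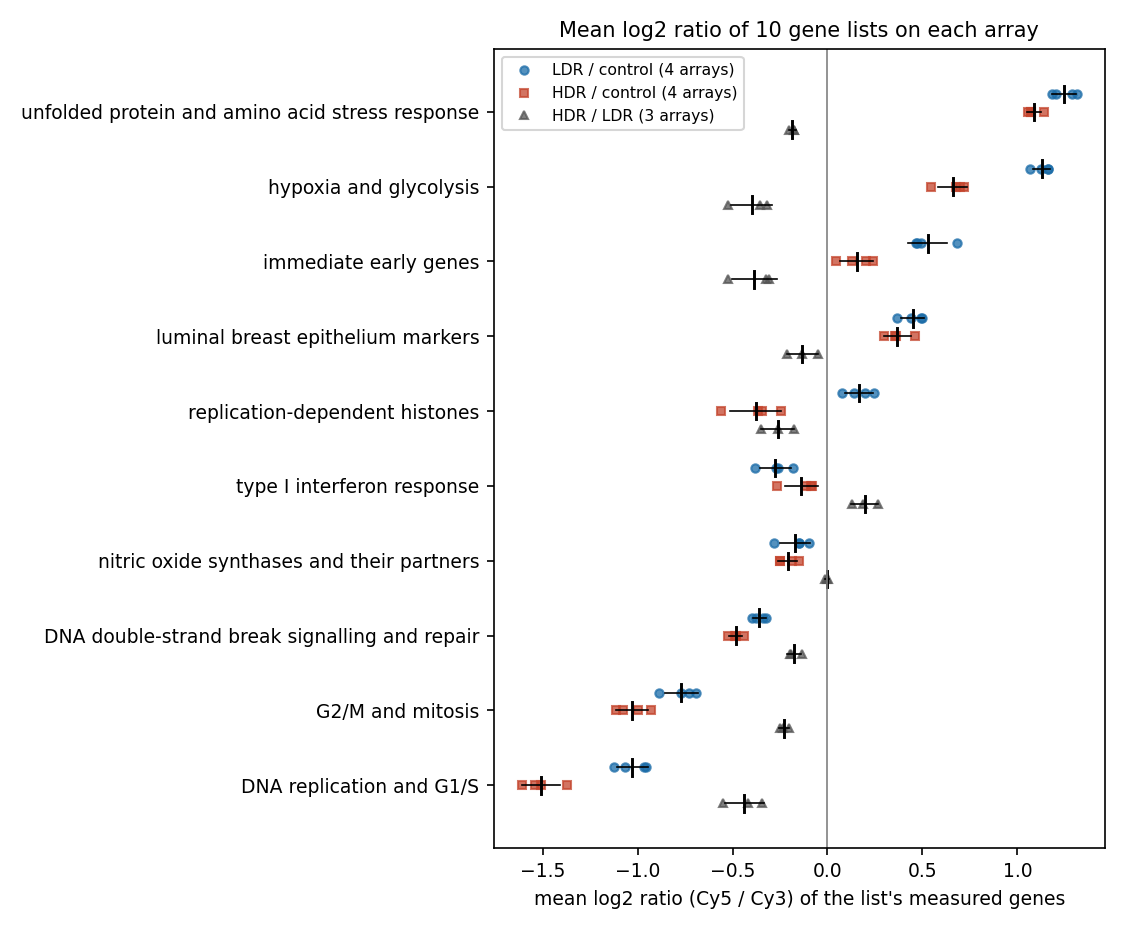
Mean log2 ratio of 10 gene lists on each array (x axis, Cy5 over Cy3), with circles for LDR over control, squares for HDR over control and triangles for HDR over LDR; ticks mark means and lines the SD. Hypoxia and glycolysis genes lay at 1.07 to 1.16 on the arrays of LDR over control and at 0.54 to 0.72 on those of HDR over control; with median centring alone the list's median in HDR over LDR, -0.38, was -0.09 relative to all genes (raw 0.29).

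Both irradiated groups shared many of their differences from the control. Control RNA was in Cy3 in both comparisons, so a shift of the control cultures would enter both. Such a shift cannot be told apart here from what the exposures have in common. LAMP3, CLGN and CITED2 were among the 12 largest rises in both, and CDC25A, E2F2, UHRF1 and SAPCD1 among the 12 largest falls in both. Of the genes tested, 8697 were called in the same direction in both comparisons (3751 higher and 4946 lower) and 420 in opposite directions. Independent lists would share 1615.4 higher and 2165.1 lower genes. Across genes, which are not independent replicates, the log2 ratios correlated at 0.78 with a covariance of 0.1692. Simulated unchanged groups against shared controls gave 0.5 and 0.0043. The simulated controls varied only by the spread within sets of arrays, so a shift of the control cultures was not simulated. Sets of arrays with no replicate number in common gave correlations of 0.72 and 0.7 and covariances of 0.1591 and 0.1631. In the dye-free estimates 4180 genes were called in the same direction in both. Both estimates share the HDR against control and HDR against LDR arrays, with the same signs. Part of that agreement is therefore built in, and no unchanged groups were simulated for it.

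**Figure D3:**
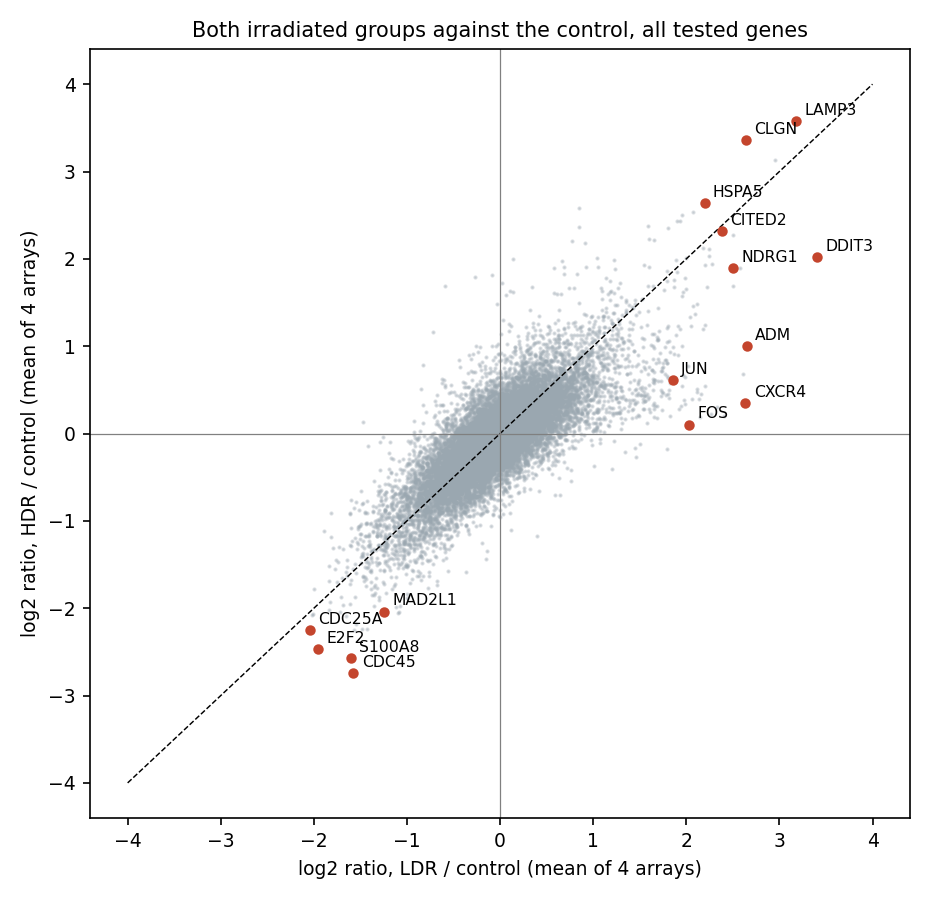
Mean log2 ratios of all tested genes in HDR over control (y axis, 4 arrays) against LDR over control (x axis, 4 arrays), with equality dashed and 15 genes named. LAMP3 lay at 3.18 and 3.58, CXCR4 at 2.63 in LDR, and CDC45 at -2.74 in HDR.

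HDR against LDR asks which transcripts separated the recent high-dose-rate exposure from the earlier low-dose-rate one. JUN and FOS, the subunits of the transcription factor AP-1, fell by 1.57 ± 0.14 (adjusted p = 0.000155) and 1.5 ± 0.5 (adjusted p = 0.000544), CXCR4 by 1.7 ± 0.83 (adjusted p = 0.0012) and ADM by 1.36 ± 0.28 (adjusted p = 0.000549). MEIOB, a meiotic recombination gene, had the largest rise (1.25 ± 0.26, adjusted p = 0.000122). In all, 2127 of 20990 genes were called, 1389 higher in HDR (65.3%) and 738 lower, and 15 of them had at least a 2-fold difference (3 higher, 12 lower). The count fell to 559, 724 and 1050 when replicate 1, 2 or 3 of this comparison was left out. Median centring alone called 13357 genes, 83.6% of them higher, and put the median of all genes at 0.38, so that list medians under it are given relative to that shift, with raw values in brackets.

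Further falls in HDR against LDR were those of CCN1 (-1.19 ± 0.41), the lipid droplet gene HILPDA (-1.15 ± 0.58) and the small nucleolar RNA gene SNORD14E (-1.07 ± 0.42). They were followed by the mRNA decay factor ZFP36 (-1.06 ± 0.19), CDC45 (-1.05 ± 0.22), the phosphatase DUSP1 (-1.05 ± 0.27), the endothelin EDN2 (-1.05 ± 0.29) and the WNT inhibitor DKK1 (-0.98 ± 0.3). Further rises were those of DUSP13A (1.14 ± 0.37), SPINK4 (1.04 ± 0.06), GJE1 (0.99 ± 0.43), the potassium channels KCNK5 (0.98 ± 0.32) and KCNQ1 (0.95 ± 0.44), with SUSD3 (0.94 ± 0.1) next. Close to these lay TESMIN (0.92 ± 0.3), PREX1 (0.91 ± 0.18), OPLAH (0.91 ± 0.09), KLK8 (0.91 ± 0.22) and CLGN (0.89 ± 0.12). Without replicate 1 of this comparison KCNQ1 (adjusted p = 0.0592), HILPDA (adjusted p = 0.0562) and SNORD14E (adjusted p = 0.0915) were no longer called, and without replicate 2 HILPDA (adjusted p = 0.156) and SNORD14E (adjusted p = 0.109) were not.

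DNA replication and G1/S genes were lower in HDR than in LDR for 21 of 30 and higher for none, 23 adjusted over the list alone, with a median of -0.46 that was -0.25 relative to all genes with median centring alone (raw 0.13). Camera gave adjusted p = 8.18e-22, and adjusted p = 0.0254 with an estimated correlation. The ribonucleotide reductase subunit RRM2 fell by 0.78 ± 0.14 and MCM5 by 0.66 ± 0.14. Hypoxia and glycolysis genes were lower for 19 and higher for 1 of 30 (22 and 1 adjusted over the list alone), with a median of -0.38 that was -0.09 relative to all genes with median centring alone (raw 0.29). Camera gave adjusted p = 4.26e-17, and adjusted p = 0.0254 with an estimated correlation. KDM3A fell by 0.6 ± 0.14, and the carbonic anhydrase CA12 rose by 0.59 ± 0.07. Immediate early genes were lower for 10 of 28 and higher for none, 12 adjusted over the list alone (adjusted p = 1.98e-08; adjusted p = 0.0666 with an estimated correlation), and their median of -0.18 stayed below 0 under each of the other 4 scalings. Beside JUN, FOS and ZFP36, KLF6 fell by 0.75 ± 0.07.

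Double-strand break signalling and repair genes were lower in HDR than in LDR for 8 and higher for 1 of 30 (11 and 1 adjusted over the list alone; adjusted p = 4.81e-07, and adjusted p = 0.0254 with an estimated correlation), and their median of -0.13 was -0.06 relative to all genes with median centring alone (raw 0.32). Through the control this list passed camera only without saturated probes (adjusted p = 0.0558, and 0.0345 without them, or adjusted p = 0.258 with an estimated correlation). CHEK1 fell by 0.7 ± 0.11 and RAD54L by 0.67 ± 0.11, and the end-resection factor RBBP8 rose by 0.5 ± 0.07. G2/M and mitosis genes were lower for 11 of 31, 18 adjusted over the list alone (adjusted p = 6.76e-12; adjusted p = 0.0642 with an estimated correlation), with CDK1 at -0.58 ± 0.04, and their median was -0.01 relative to all genes with median centring alone (raw 0.37). Replication-dependent histones were lower for 5 of 20, 9 adjusted over the list alone (adjusted p = 9.02e-08; adjusted p = 0.0852 with an estimated correlation), with H4C14 at -0.59 ± 0.24, and their median was -0.05 relative to all genes with median centring alone (raw 0.33). NF-kappaB and inflammatory secreted factors were lower for 5 of 21 (adjusted p = 3.42e-05; adjusted p = 0.157 with an estimated correlation), with TNF at -0.9 ± 0.29 and LTB at -0.64 ± 0.22, and the sign of their median held under the other 4 scalings. Type I interferon response genes were higher for 7 and lower for 1 of 30, 15 and 2 adjusted over the list alone (adjusted p = 0.000119; adjusted p = 0.175 with an estimated correlation). The sign of their raw median also held under the other 4 scalings. Median centring alone raised the median of all genes to 0.38, so a kept positive sign there says little. MX1 rose by 0.7 ± 0.13 and IFITM1 by 0.59 ± 0.21, and IRF1 fell by 0.39 ± 0.18; without replicate 1 IFITM1 was not called (adjusted p = 0.105), and without replicate 2 IRF1 was not (adjusted p = 0.0704).

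Unfolded protein and amino acid stress response genes were lower for 5 of 30 in HDR (adjusted p = 1.73e-05, and adjusted p = 0.0254 with an estimated correlation), with ATF3 at -0.94 ± 0.08 and PPP1R15A at -0.72 ± 0.25, but the list's median turned from -0.12 to 0.26 relative to all genes with median centring alone. Cholesterol synthesis genes were lower for 7 and higher for 2 of 29 (adjusted p = 0.000119; adjusted p = 0.136 with an estimated correlation), with IDI1 at -0.69 ± 0.1; median centring alone turned the median to 0.16 relative to all genes, while IDI1 was -0.37 relative to them (raw 0.01). Heat shock chaperones were lower for 4 of 19 (adjusted p = 0.000155; adjusted p = 0.0642 with an estimated correlation), with HSPA1A at -0.96 ± 0.22, and luminal markers were lower for 4 and higher for 2 of 23 (adjusted p = 0.00413; adjusted p = 0.184 with an estimated correlation), with ELF3 at -0.9 ± 0.25; median centring alone turned these medians to 0.18 and 0.3 relative to all genes. The heat shock call was lost without saturated probes (adjusted p = 0.11). Through the control, the heat shock, luminal and unfolded protein lists did not pass camera (adjusted p = 0.532, 0.648 and 0.129), but without saturated probes the luminal and unfolded protein lists did (adjusted p = 0.04 and 0.0177; adjusted p = 0.431 and 0.167 with an estimated correlation). Cytoplasmic ribosomal protein genes were lower for 16 of 35 on these arrays (adjusted p = 2.86e-11; adjusted p = 0.184 with an estimated correlation) but higher for 26 through the control, and most of their probes were saturated. The 5 members without saturated probes had a median of -0.533 through the control (camera adjusted p = 0.0288, or adjusted p = 0.167 with an estimated correlation). The p53 target genes had 5 higher and 1 lower of 30 and did not pass camera (adjusted p = 0.629), with TP53I3 at 0.68 ± 0.1 and TP53INP1 at 0.61 ± 0.14. Oestrogen and progesterone receptor signalling had 6 higher and 2 lower of 28 (adjusted p = 0.162, but 0.0251 through the control and 0.0447 without saturated probes), with IGFBP5 at 0.62 ± 0.05. Both calls were lost (adjusted p = 0.296 and 0.276) with an estimated correlation.

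TGF-beta signalling genes had 2 higher and 4 lower of 24 between HDR and LDR (adjusted p = 0.0897, and 0.0325 without saturated probes, or adjusted p = 0.0947 with an estimated correlation), with the inhibitor of differentiation ID1 at -0.72 ± 0.08, or -0.3 relative to all genes with median centring alone (raw 0.08). Antioxidant genes had 2 higher and none lower of 35 (adjusted p = 0.114), and BCL2 family and caspase genes 2 and none of 28 (adjusted p = 0.526). Metallothioneins had 2 and none of 12 (adjusted p = 0.6), basal and mesenchymal markers 1 and none of 17 (adjusted p = 0.318), and blood and endothelial cell markers none of 12 (adjusted p = 0.895). Through the control, with a dye effect removed and on arrays scanned on 1 day, 5068 of 20987 genes were called, 2288 higher in HDR (45.1%) and 2780 lower. LDR and HDR arrays against the control lay on different slides, so a slide difference stays in this estimate. Median centring alone called 2335 genes through the control, 15.2% of them higher. There the hypoxia list was lower for 18 and higher for 1 gene, with a median of -0.48, and the replication list lower for 22, with a median of -0.47. Replication-dependent histones were lower for 15 of 20, with a median of -0.53. The medians of these 3 lists stayed below 0 under each of the other 4 scalings. Camera gave adjusted p = 5.47e-08, 2e-09 and 2e-09, and adjusted p = 0.183, 0.271 and 0.183 with an estimated correlation. Of the 2127 genes called on the direct arrays, 85.1% had the same direction through the control, 1147 were also called there and 122 were called in the opposite direction. The 15 genes with at least a 2-fold difference all had the same direction, and 14 of them were called.

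**Figure D4:**
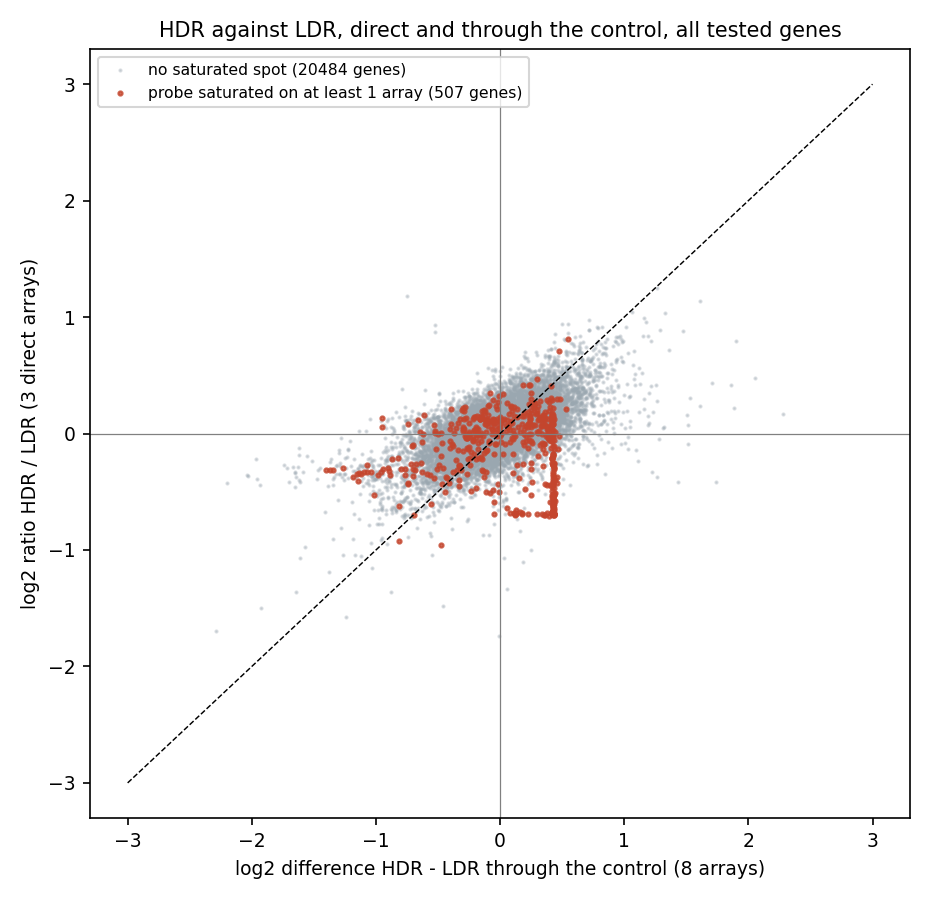
Log2 ratios of all tested genes in HDR over LDR on the 3 direct arrays (y axis) against the log2 difference through the control on 8 arrays (x axis), with equality dashed. Genes whose probe was saturated on at least 1 array (507, in red) include a group at about -0.7 on the direct arrays and 0.43 through the control.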

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

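The tests of chance values from shared control RNA, of 1 axis of response and of the slide or the dye were chosen only after the result was seen, and the other tests were named before. Both irradiated groups differed from the control in the same direction for 8697 genes, among them rises of LAMP3 and CLGN and falls of E2F2 and CDC25A. A single dye effect on every array would shift HDR over LDR as it shifts the comparisons with the control, but the slope across genes was -0.01. Chance values of shared control RNA would give a covariance near the simulated one. Arrays with no replicate number in common kept 0.95 of the observed covariance instead. The state of the control cultures could also have produced these differences, and 0 slides held more than 1 comparison, so this cannot be told apart from the irradiation itself.

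HDR was lower than LDR in 2 lists on opposite sides of the control: the mean of the hypoxia list fell from 1.13 ± 0.04 in LDR to 0.66 ± 0.08 in HDR, and that of the replication list from -1.03 ± 0.08 to -1.51 ± 0.1. One axis of response with a different size in each group would move them in opposite directions, but both were lower in all 4 pairs of same-numbered arrays, by -0.47 ± 0.11 and -0.48 ± 0.12 (exact paired p = 0.125 for each, the smallest that 16 assignments allow), a value seen on these arrays before the test was chosen. An effect of the slide or of the dye could give one of the estimates, but the direct arrays had a median of -0.38 for the hypoxia list. The normalization could also matter: with median centring alone the higher of the 2 medians through the control was -0.69, while the direct arrays gave raw medians of 0.29 for hypoxia and 0.13 for replication (-0.09 and -0.25 relative to all genes). Dose rate and time since exposure differ together and stay open.

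Genes called in opposite directions on the direct arrays and through the control numbered 122, and 68% of them had a probe saturated on at least 1 array, against 2.42% of all tested genes. The 29 genes saturated in both channels on every array had a median of -0.69 on the direct arrays and 0.43 through the control. This fits saturated spots as the source for most of these genes, and the remaining opposite calls could have another cause that stays open.

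Regrouping the arrays was possible for few splits. In LDR against control the real grouping called 12850 genes and the highest other 1, and it was 1 of 8 splits. In HDR against control these values were 12284 and 6, again 1 of 8, and in HDR against LDR 2127 and 0, 1 of 4, and each has too few splits to tell. Between HDR and LDR through the control the real grouping was 1 of 35, with 3741 genes in a fit of these arrays alone and 0 in any other split. That argued against chance only if all 35 splits are exchangeable; the splits that part all 4 pairs, the real one included, number 8 and are too few to tell.

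Single arrays stood apart from the other 3 in 18 of 264 groups of 4 arrays, where about 1 in 20 would by chance. In LDR against control, replicate 2 accounted for 9 of 10. Among them, it was higher for the immediate early list (0.68, others 0.47 to 0.49), JUN (2.42, others 1.65 to 1.69), ID2 (1.72, others 1.11 to 1.2), DNAJB9 (2.15, others 1.89 to 1.91) and TNFRSF10B (0.73, others 0.61 to 0.62). It was closer to 0 for GDF15 (2.8, others 2.99 to 3.02), MVK (-0.93, others -1.11 to -1.09) and RAD54L (-0.86, others -1.09 to -1.07). CLGN was lower on replicate 3 (2.5, others 2.67 to 2.7). In HDR against control, replicate 2 was lower for the interferon list (-0.27, others -0.11 to -0.08), MT1E (-0.85, others -0.49 to -0.46) and MT1F (0.27, others 0.59 to 0.63), and closer to 0 for NFKBIE (-0.41, others -0.64 to -0.63). Replicate 1 was higher for the unfolded protein response list (1.14, others 1.06 to 1.07) and lower for LGR4 (2.07, others 2.69 to 2.8). Replicate 4 was lower for CDH15 (1.93, others 2.47 to 2.57) and closer to 0 for CCL2 (-0.43, others -1.31 to -1.17). No cause was tested for these values.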

How the results depend on the processing

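The tests without saturated probes, at 2-fold and with the replicate block on the arrays against the control alone were chosen only after the result was seen; where no cause is given, the cause was not tested. Counts of genes called in HDR against LDR, against 2127, were 3552 with no background correction, 5054 with the scanner software's log ratio, 3551 with the authors' values, 13357 with median centring alone, 4042 in a separate fit, 5374 with array weights, 5068 in the dye-free estimate and 4638 with direct and indirect evidence joined. A fold of at least 1.5 left 304 and of at least 2 left 15. Through the control, against 5068, median centring alone gave 2335, at least 1.5-fold 1134 and at least 2-fold 204. The closure of the 3 comparisons, against 742 genes, gave 12771 with median centring alone and 1420 with array weights. HDR against control, against 12284, gave 4942 in the dye-free estimate, 3373 at 1.5-fold and 909 at 2-fold. LDR against control, against 12850, gave 3782 at 1.5-fold and 1059 at 2-fold. The overlap of 8697 became 4180 in the dye-free estimates, which share arrays, so that part of this count is built in. Dye-free estimates are less precise than direct ratios, so lower counts in them need not reflect a dye effect. Leaving out single arrays gave 11370 to 13076 for LDR against control, 10674 to 12833 for HDR against control, 559 to 2692 for HDR against LDR, 3544 to 5026 through the control and 311 to 767 for the closure. The lowest HDR against LDR counts were those without its own replicates 1 (559), 2 (724) and 3 (1050), and without any of these, or without replicate 4 of LDR against control (434), the closure fell to 340, 404 and 311. Aquantile leaves the ratios unchanged by construction. Signals near background limit what can be said of NOS1 and NOS2, and saturated spots what can be said of ribosomal protein genes.

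With the replicate number as a block, 13319 genes were called in LDR against control, 12796 in HDR against control, 1931 in HDR against LDR, 5871 through the control and 1103 in the closure. With the block on the 8 arrays against the control alone, whose numbers pair, the counts were 13930, 13533 and 7187 through the control. In the first of these paired fits FCER1G in HDR against control (adjusted p = 0.0677) and NQO1 (adjusted p = 0.0582), CD44 (adjusted p = 0.0694) and MT3 (adjusted p = 0.0507) in HDR against LDR were no longer called, and no other call of a named gene was lost.

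Signs changed as follows. NOS1 in HDR against control was 0.04 with no background correction and with the authors' values, 0.2 with the scanner software's log ratio, 0.02 with median centring alone (0.15 relative to all genes) and between -0.03 and 0.01 with single arrays left out, above 0 without replicate 2. NOS3 in HDR against LDR was -0.01 with the scanner software's log ratio, -0.02 with evidence joined, between -0.02 and 0.03 with single arrays left out (below 0 without replicate 1) and -0.07 in the dye-free estimate, and in HDR against control -0.04 with median centring alone (0.09 relative to all genes) and -0.04 in the dye-free estimate.

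Median centring alone put the median of all genes in HDR against LDR at 0.38, and gave some genes another raw sign there. Still lower relative to all genes were IDI1 0.01, INSIG1 0.09, RPLP1 0.3, CDK1 0.16, TPX2 0.31, FOXM1 0.14, HSPH1 0.34, PGK1 0.26, KLF6 0.01, NFKB1 0.13, FKBP5 0.01, ID1 0.08 and ID2 0.09 (raw values). Above the shift lay CCNB2 0.48, HSPA8 0.54, HSPB1 0.56, KRT18 0.55, GDF15 0.54, H2AC18 0.39 and ATF4 0.4. Of these, RPLP1, HSPA8, KRT18 and ATF4 had saturated Cy5 spots on all 3 arrays, so their values are not exact. Among others, the dye-free estimate turned SLC30A1 (-0.04) in LDR against control, and in HDR against LDR GPX3 -0.01, MT3 -0.04, CXCL12 -0.04 and GDF15 0.18, which rests on 1 array of HDR against control. List medians that turned in the dye-free estimate were those of blood and endothelial markers (-0.038), heat shock chaperones (0.012), p53 targets (-0.004) and histones (-0.173) in LDR against control, of antioxidant genes (-0.048), the BCL2 family (-0.193) and heat shock chaperones (0.034) in HDR against control, and of antioxidant genes (-0.007), blood and endothelial markers (-0.035), ribosomal proteins (0.425) and nitric oxide synthases and partners (-0.027) in HDR against LDR. Without saturated probes, the ribosomal protein median turned to -0.331 in HDR against control and to 0.068 in HDR against LDR, where its call was lost (adjusted p = 0.898). Over all settings the named genes kept sign and call in 3081 values in LDR against control. The values were 3182 in HDR against control and 2361 in HDR against LDR. In the same order, 15, 34 and 115 were weaker, 7, 0 and 0 stronger and 2, 7 and 30 of the opposite sign. Many settings leave a gene's ratio unchanged, such as Aquantile or leaving out an array of another comparison, so these totals overstate stability. Without its own replicate 1, 2 or 3, HDR against LDR lost 26, 24 and 15 calls among 87 named genes.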

Other observations

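Gene families that share a symbol were tested as 92 sets chosen only after the result was seen, and none passed camera with an estimated correlation. Cytoplasmic tRNA synthetase genes, which charge tRNAs with amino acids, were higher for 12 and lower for 1 of 17 in LDR (median 0.77, adjusted p = 0.0019; adjusted p = 0.718 with an estimated correlation). In HDR they were higher for 11 and lower for 1 (median 0.45, adjusted p = 0.00243; adjusted p = 0.505 with an estimated correlation). AARS1 was 1.52 in LDR and 1.09 in HDR, WARS1 1.45 and 1.52, and SARS1 1.06 and 1.19. Mitochondrial ribosomal protein genes were lower for 46 and higher for 9 of 78 in LDR (median -0.21, adjusted p = 0.00221; adjusted p = 0.718 with an estimated correlation). In HDR 57 were lower and 11 higher (median -0.42, adjusted p = 7.89e-07; adjusted p = 0.505 with an estimated correlation), with MRPS25 at -0.95 and -1.14. These medians kept their sign under each of the other 4 scalings.

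Genes of respiratory complex I (NDUF symbols) were lower for 29 of 45 in LDR (median -0.25, adjusted p = 0.00421) and for 34 in HDR (median -0.4, adjusted p = 3.71e-06), with NDUFS6 at -0.81 and -1.03. Proteasome subunit genes were lower for 24 of 38 in LDR (median -0.35, adjusted p = 0.00307) and for 26 in HDR (median -0.4, adjusted p = 4.53e-05), with PSMB6 at -0.89 and -1.08. Nucleoporin genes were lower for 16 of 21 in HDR and higher for none (median -0.38, adjusted p = 0.000434), with NUP85 at -0.82 and NUP107 at -0.73. In LDR nucleoporin genes were lower for 8 and higher for 3 (adjusted p = 0.477), but in the dye-free estimate for 12 and none (adjusted p = 0.0131; adjusted p = 0.666 with an estimated correlation). Signs of these medians against the control also held under the other 4 scalings, and no family call was kept with an estimated correlation.

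Spike-in probes added to every array had a mean log2 ratio of 0.62 ± 0.16 in LDR against control, 0.01 ± 0.52 in HDR against control and -0.01 ± 0.21 in HDR against LDR. The amounts added are not given in the sources, so no level was taken from them.

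One hypothesis is that the control cultures were less stressed than both irradiated groups at harvest, because 0 slides held more than 1 comparison and this could not be separated from irradiation. Control cultures harvested at 24 h and at 2 months, hybridised on slides that mix the groups, would test it through DDIT3, HSPA5 and NDRG1. Another hypothesis is that the response splits into parts that depend on time or on dose rate, prompted by the hypoxia list lying lower by -0.47 within pairs, and not tested on other data. Both dose rates harvested at both times, with dyes swapped, would test it through ADM, JUN, RRM2 and the histone genes. NOS3 RNA did not pass the threshold in any comparison as planned, though it did for LDR against control in several alternatives, and enzyme activity was not measured by these arrays. An assay of nitrite or of labelled citrulline in the 3 kinds of cells would test whether activity differs.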
